A study of Mus musculus with 16 samples.

How the data were processed

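Gene expression was measured in CD4+ T cells from mouse spleen with a 1-colour (Cy3) Agilent whole-genome array, 1 array per sample. Per the labels, the mice were males of 8 to 10 weeks that carried CD4-Cre alone or CD4-Cre with a floxed gene of the IkB kinase complex: Ikbkb, which encodes the kinase IKK2, or Ikbkg, which encodes the regulatory subunit NEMO. CD4-Cre is active from the stage of thymocyte development at which CD4 is made, so the floxed gene is deleted in T cells. Some mice were injected with nephrotoxic serum from sheep at a dose of 2.5 mg for each g of body weight, which induces an immune-mediated glomerulonephritis, and were sampled on day 10. Spleen CD4+ T cells were enriched with an isolation kit and then sorted, RNA was extracted with 1 of 2 kits chosen by cell number, and 0.1 µg of RNA with an integrity number of at least 8 was labelled, per the labels' protocols. The labels do not tie a kit to a sample, and the submitters state that deletion was checked by PCR.

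The authors deposited the scanner output of each array, whose values are spot intensity on a linear scale. Per the file headers, the processed intensity had been background-subtracted and detrended by Agilent Feature Extraction. Per the submitters' processing notes the version was 10.5, whereas the file headers give a later one. The authors also deposited a matrix of log2 values for the same 16 arrays, whose method is not given in the sources used here. Its column medians lay between 5.65 and 5.68 and its columns correlated at 0.994 to 0.999, across probes, with the log2 median spot intensity of the same array. It correlated at 0.966 to 0.984 with the log2 processed intensity, which places it on a log2 scale, equalised between arrays and without gene centring. Whether and how background was treated in it stays unknown. It had 4 missing cells and held all 55681 probes, and it served as an alternative only.

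Each array had 62976 spots, of which 59305 were not controls. Control spots and spots marked as outliers by the scanner software (103 to 246 per array) were left out, and no spot was saturated. Spots of 1 probe were averaged. On each array, 48.9% to 59.8% of spots were well above background, and the 75th percentile of the processed intensity lay between 265 and 477. The coefficient of variation of replicate spots was 4.15% to 10.7%. The mean net signal of the negative controls followed the slide, at 40.5 to 46.0 on slide 1, 19.5 to 22.4 on slide 2 and 16.4 to 17.7 on slide 3. The number of arrays, 2 or 3 per group, limits the precision.

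The processed intensity was taken to log2 and each array's 75th percentile over non-control probes was subtracted. Gene names came from the array files and were updated through a RefSeq table of mouse assembly GRCm38.p6, while the file headers name build mm9, so that table served for names and gene order only and no coordinates are given. Of the 55681 probes, 27235 had 1 symbol and 28446 had none here, and 20660 genes had a probe. A gene was represented by its probe with the highest mean over the 16 arrays, among probes well above background on at least 2 arrays (34938 probes, 14675 genes). Where a named gene had several probes, all others had the same sign in 113 of 122 cases of gene and comparison, and another probe had the opposite sign in 9, of which 2 reached an unadjusted p under 0.05.

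A linear model of the 6 group means was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, 11.8 residual plus prior degrees of freedom) in R 4.3.3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots. P values are two-sided and were adjusted by Benjamini-Hochberg over the 14675 genes within a comparison, with a threshold of 0.05. All adjusted p values in the text come from this limma model or from limma's camera. Differences are log2 values with the model's standard error (SE), and group levels are means with the standard deviation (SD). Comparisons between nephritic and untreated mice were made within each genotype, each knockout was compared with Cre controls of the same condition, the knockouts were compared with each other under nephritis, and the difference of the nephritis response between knockout and control was tested as a contrast of its own. All of these comparisons share 1 variance estimate per gene, and those against the same control group share its arrays. Nothing in the labels says whether the arrays of a group came from separate animals, so p values measure only the spread between these samples, which may be technical.

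A gene whose probes were not well above background on any array of 1 group has only a bound. Its fold is given as "at least" the ratio of the mean of the brighter group to a floor, where the floor is the mean over the dim group of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, all on the normalised log2 scale.

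Gene lists (23 lists, 385 genes, 374 with a probe, 5 symbols updated through synonyms) were fixed before the data were examined. They cover noncanonical NF-kB components, canonical NF-kB components, NF-kB target genes, Th1, Th2, Th17, regulatory T cell, follicular helper T cell, naive and central T cell, antigen-experienced T cell, cell cycle, interferon response, apoptosis regulators, glycolysis, T cell identity, and immediate early and heat shock genes. Markers of other cells that a spleen sort could hold were B cell, plasma cell, myeloid cell, dendritic cell, CD8 and NK cell, erythroid and platelet markers. Lists overlap: 16 of the 30 NF-kB target genes and 6 of the 25 antigen-experienced T cell genes also stand in another list. List shifts were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists within a comparison, and again with an estimated correlation. For camera alone, 27 missing values were filled with the group mean. No list shift called at the preset correlation was called with an estimated correlation. The direction of camera's test is relative to all other genes.

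The genes named were fixed by a rule set before the data were examined. Per comparison, these were the 6 largest rises and 6 largest falls past the threshold whose group values did not overlap (not asked of response differences), leaving out predicted and unnamed transcripts. Up to 4 members of each list with the smallest adjusted p past the threshold, and any NF-kB component past it, were added. Ikbkb and Ikbkg were always included. The groups, the comparisons, the tests and most alternatives were likewise set before the data were examined.

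The 3 slides were treated as batches. Slide 1 held all Cre and IKK2 arrays with nephritis and 2 untreated IKK2 arrays, slide 2 held the untreated Cre arrays and 1 untreated IKK2 array, and slide 3 held the 4 NEMO arrays only. Slide was used as a fixed block where a comparison could be estimated with it, as a random block (correlation within slide 0.161), and by fitting 1 slide alone. Slides 1 and 2 shared only the untreated IKK2 group, so the fixed block's offset between them rests on its replicate 3 against replicates 1 and 2. Other alternatives were normexp background correction (offset 50) on the median spot signal, because no mean spot signal column was found in the files, quantile normalisation, the authors' matrix, no filter or a filter of 8 arrays on dim probes, and a percentile over probes well above background on all arrays. Further ones were the replicate number as a block, only the arrays of the groups compared, all probes, a 2-fold threshold and leaving out each array. The omission of 2 arrays that stood apart and a B cell marker covariate were chosen after seeing the data.

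The scripts were tested on simulated data. With 67, 67 and 66 of 14648 real genes changed by 0.5, 1 and 2 on the log2 scale, the IKK2 comparison under nephritis recovered 35.8%, 77.6% and 89.4% of them, with 9 false calls. The NEMO comparison under nephritis recovered 23.9%, 70.2% and 77.3% with 10 false calls. The response difference of the IKK2 knockout recovered 14.9%, 49.3% and 72.7% with 6 false calls, and that of the NEMO knockout 1.49%, 37.3% and 59.1% with 5. A shift of 0.5 given to the cell cycle list in the IKK2 comparison under nephritis was called, with no call among the 22 other lists. The simulated genes varied independently and without slide effects. These tests check the scripts and do not show how often genes or correlated lists are called wrongly in the real arrays. The values of 3 single genes are not reported here, though these genes stayed in the fits, the gene lists and the counts.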

Results

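Transcript levels were measured on 16 arrays of splenic CD4+ T cells, in 6 groups defined by genotype and disease. Cre control and IKK2 knockout mice each had 3 arrays without nephritis and 3 arrays on day 10 of nephrotoxic serum nephritis. NEMO knockout mice had 2 arrays in each condition. IKK2 is a catalytic subunit and NEMO the regulatory subunit of the kinase complex that activates canonical NF-kB, and the series title sets NEMO apart from IKK2 through the noncanonical NF-kB pathway. Of 14675 genes tested, between 39 and 7095 passed an adjusted p of 0.05, depending on the comparison. Pearson correlations between arrays of a group, across genes, lay between 0.971 and 0.993. The first principal component held 49.1% of the variance and separated the 4 NEMO arrays (71.8 to 90.2) from all others (-51.9 to 7.88). Cre control replicate 2 with nephritis stood apart on the third component, at -67.4.

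The targeted genes were measured first. The Ikbkb level was 3.30 ± 0.01 (SD, n = 3) in Cre control arrays and 3.06 ± 0.22 (n = 3) in IKK2 knockout arrays without nephritis, a difference of -0.24 (SE 0.11) with an exact permutation p of 0.3. With nephritis it was 3.30 ± 0.14 and 2.96 ± 0.06, a difference of -0.34 (SE 0.11) with an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. These differences did not pass in the limma model (adjusted p = 0.162 and 0.133). In NEMO knockout arrays Ikbkb was 2.95 ± 0.16 and 2.82 ± 0.06 (n = 2 each), lower than in controls by limma (-0.35, adjusted p = 0.0371, and -0.48, adjusted p = 0.00653). The Ikbkg probe used here read -0.84 ± 0.14 in NEMO knockout arrays against -0.70 ± 0.17 in controls without nephritis (adjusted p = 0.337). With nephritis it read -0.65 ± 0.09 against -0.31 ± 0.08 (adjusted p = 0.0195), and the difference of a weaker second probe was 0.015 there, so that the fall was not seen on both probes. In the IKK2 knockout without nephritis Ikbkg was higher than in controls by 0.68 (SE 0.10, adjusted p = 0.00153) and by 0.34 on the second probe. No source used here places these probes inside the deleted parts of the genes, and a probe outside them checks nothing about the deletion.

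**Figure D1:**
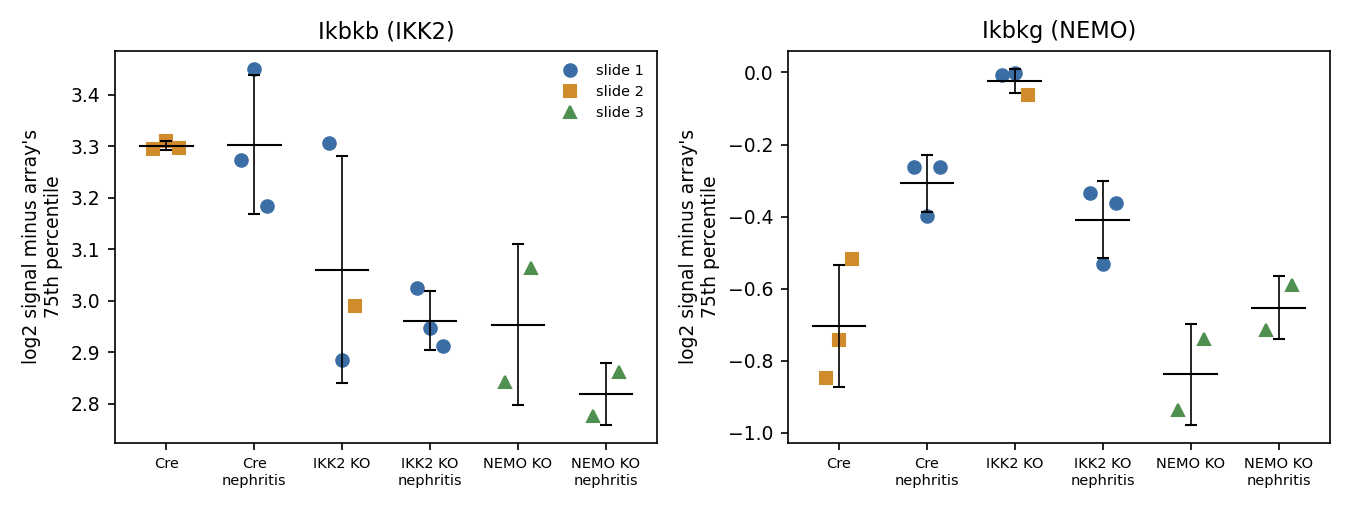
Log2 level of Ikbkb (left) and Ikbkg (right) on each array by group, relative to the array's 75th percentile, with group means and SD and points coloured by slide. The mean Ikbkb level lies between 2.82 in NEMO knockout arrays with nephritis and 3.30 in Cre control arrays.

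The comparison of IKK2 knockout with Cre control under nephritis asked what T cells lacking IKK2 express differently during disease, and all of its 6 arrays lay on slide 1. In the knockout 7 of 27 NF-kB target genes and 7 of 19 regulatory T cell genes were lower, and both lists were called downward by camera, though not with an estimated correlation. Il2, the T cell growth factor, fell by 1.64 (SE 0.29), Lta and Ltb, which encode lymphotoxins, each fell by 0.67 (SE 0.10), and the noncanonical subunit genes Relb and Nfkb2 fell by 0.69 (SE 0.12) and 0.65 (SE 0.13). Il2ra, the high-affinity IL-2 receptor chain, fell by 1.72 (SE 0.26), and Lrrc32, which holds latent TGF-beta on regulatory T cells, by 2.34 (SE 0.34). Il1rl1, the IL-33 receptor, fell by 2.12 (SE 0.21) and Il4 by 2.07 (SE 0.34). Of other interleukin receptor genes, Il17re rose by 3.01 (SE 0.55), Il17rc by 3.14 (SE 0.60) and Il1r1 by 3.15 (SE 0.58).

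Of 27 NF-kB target genes measured, 7 fell and 20 did not pass, with 7 falling when adjusted over the list alone (list median -0.23, adjusted p = 0.00114, and adjusted p = 0.574 with an estimated correlation). Relative to untreated Cre controls, the list averaged 0.28, -0.07 and -0.28 on knockout replicates 1 to 3. It averaged 0.28, 0.15 and 0.33 on the controls, so knockout replicate 1 lay within the control range. Among 15 noncanonical components, Relb, Nfkb2 and Traf3 (-0.54, SE 0.10) fell, Tnfrsf12a rose by 0.76 (SE 0.17) and 11 did not pass, against 5 and 2 when adjusted over the list alone. The median of that list was -0.19, its mean 0.01 and its test downward (adjusted p = 0.177). Among 20 canonical components, the inhibitor genes Nfkbia (-0.32, SE 0.07) and Tnip1 (-0.61, SE 0.09) and the adaptor Bcl10 (-0.41, SE 0.09) fell and 17 did not pass (5 fell and 1 rose when adjusted over the list alone), with an adjusted p of 0.152 for the list.

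Of 19 regulatory T cell genes, 7 fell, 1 rose and 11 did not pass (12 fell and 1 rose when adjusted over the list alone). The list median was -0.92 (adjusted p = 3.22e-07, and adjusted p = 0.461 with an estimated correlation). Relative to untreated Cre controls, every knockout array (-0.75 to -0.36) lay below every nephritic control (-0.18 to 0.51). Beside Il2ra and Lrrc32, Nrp1 fell by 2.12 (SE 0.32), Nt5e, the ectonucleotidase CD73, by 1.01 (SE 0.20) and the inhibitory receptor Ctla4 by 1.18 (SE 0.27). Of 11 Th2 genes 3 fell and 8 did not pass (8 fell and 1 rose when adjusted over the list alone), among them Gata3, the Th2 master factor (-0.42, SE 0.08), with a list median of -0.50 (adjusted p = 0.000172, and adjusted p = 0.143 with an estimated correlation). Of 13 Th17 genes 2 rose and 11 did not pass, likewise when adjusted over the list alone (median 0.18, adjusted p = 0.0149, and adjusted p = 0.600 with an estimated correlation). The largest falls included Zbtb16, the transcription factor PLZF of innate-like T cells (-3.11, SE 0.27), Gcnt1 (-4.17, SE 0.69, but 0.19 on another probe), Tmem273 (-3.59, SE 0.30) and Trpm6 (-3.39, SE 0.35). The early activation marker Cd69 rose by 1.10 (SE 0.12) and the survival gene Bcl2 by 0.91 (SE 0.12), while the IL-7 receptor Il7r fell by 0.93 (SE 0.14) and the integrin Itgb1 by 1.43 (SE 0.19).

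Other list shifts were called without many single genes passing. The cell cycle list (median 0.16, adjusted p = 5.97e-05, and adjusted p = 0.600 with an estimated correlation) and the interferon list (-0.29, adjusted p = 0.00828, and adjusted p = 0.686 with an estimated correlation) had no member past the limma threshold, where 2657 of all genes had an unadjusted p under 0.05. Both groups overlapped on the cell cycle list (0.63 to 1.05 in the knockout, 0.39 to 0.83 in controls, relative to untreated Cre controls). The interferon list stood at 0.01, -0.25 and 0.61 on knockout replicates 1 to 3. Replicate 3 was thus above all nephritic controls (0.34 to 0.50). The immediate early and heat shock list shifted up (median 0.18, adjusted p = 0.00416, and adjusted p = 0.538 with an estimated correlation), with 1 of 16 genes rising, Dusp1 (1.02, SE 0.19), and 3 rising when adjusted over the list alone. Markers of other cells moved as well. The medians were 0.73 for B cell, 0.55 for myeloid, 0.71 for dendritic cell and 0.93 for platelet markers (adjusted p = 0.000121, 0.00449, 0.0107 and 0.00449, with adjusted p between 0.574 and 0.600 with an estimated correlation). The T cell identity list, at a median of -0.06 (adjusted p = 0.426), the glycolysis list (-0.07, adjusted p = 0.426) and the Th1 list (-0.14, adjusted p = 0.881) were not called.

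In all, 378 genes changed, 145 higher and 233 lower, and 59 of these were at least 2-fold higher and 63 at least 2-fold lower. A percentile over probes above background on all arrays turned this split, with 188 of 366 higher (51.4% against 38.4%). With slide as a block 400 genes passed, 340 of them shared, and 39 of the 40 named genes stayed past the threshold (not Gata2, at least 2.02-fold lower). On the arrays of slide 1 alone 73 genes passed, of which 67 were shared, and 10 of the 40 named genes, among them Il2ra, Nrp1, Il1rl1, Zbtb16 and Cd69. Without Cre control replicate 2 or 3 the count was 204 or 228, and without IKK2 knockout replicate 1, 2 or 3 it was 232, 121 or 206. Without both arrays that stood apart (Cre control replicate 2 with nephritis and replicate 1 without) it was 208. It was 202 with normexp background correction, 198 with no filter on dim probes, 145 with the B cell marker mean as a covariate and 49 when only the arrays compared were fitted.

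**Figure D2:**
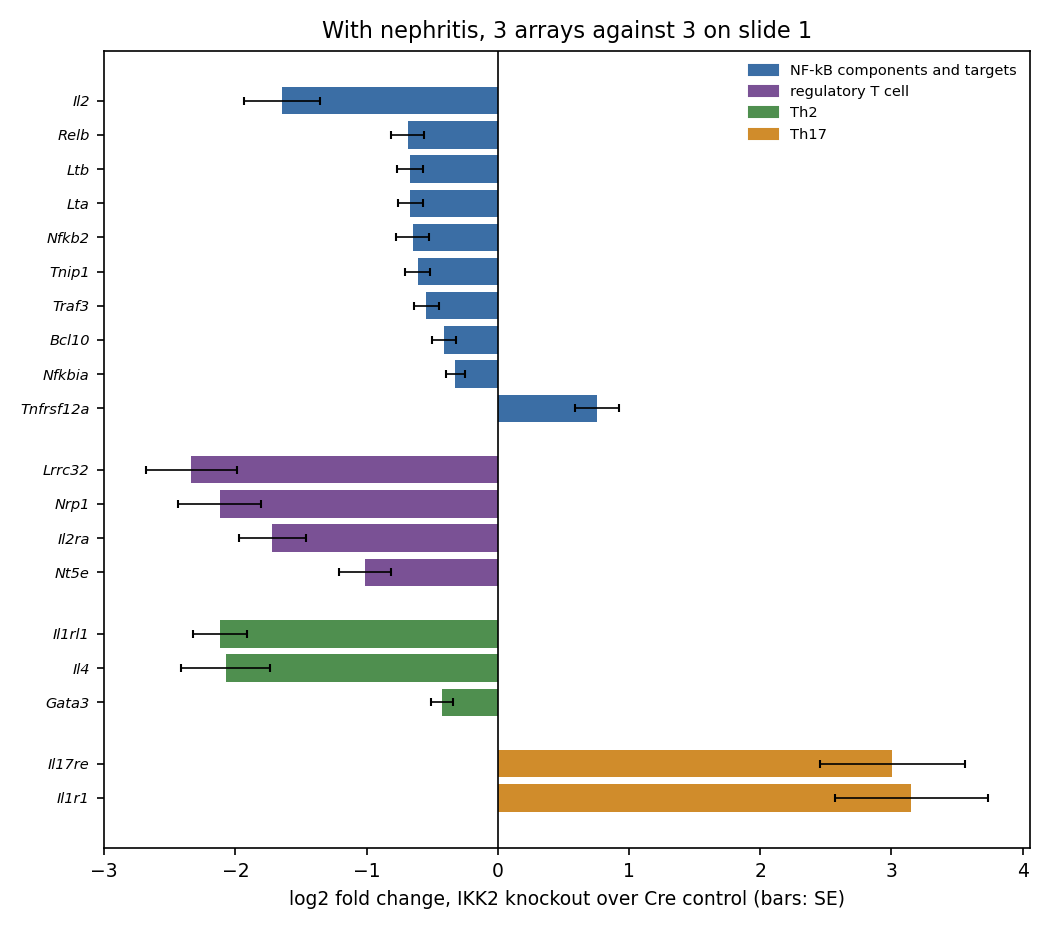
Bars give the log2 difference between IKK2 knockout and Cre control with nephritis (3 against 3 arrays, all on slide 1) for NF-kB, regulatory T cell, Th2 and Th17 genes, with the SE of the limma model as error bars. Il1rl1 lies at -2.12 and Lrrc32 at -2.34, whereas Il17re lies at 3.01.

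Without nephritis, the IKK2 knockout was compared with Cre controls to ask which differences are present without disease. Some genes downstream of NF-kB were again lower, with falls of 0.80 (SE 0.07) for Nfkbia, 1.67 (SE 0.29) for Il2, 0.50 (SE 0.10) for both Lta and Ltb, 0.51 (SE 0.12) for Relb and 0.73 (SE 0.16) for the NF-kB inhibitor Tnfaip3. Il4 fell by 3.29 (SE 0.34), Zbtb16 by 2.74 (SE 0.27), Il7r by 1.27 (SE 0.14), Il2ra by 1.40 (SE 0.26) and Lrrc32 by 1.98 (SE 0.34). Genes of B cells rose together, including the B cell receptor signalling component Cd79b (2.56, SE 0.25), and so did mitotic genes such as Bub1 (1.72, SE 0.21) and the myeloid lysozyme Lyz2 (3.37, SE 0.54). Il17re (2.76, SE 0.55) and Il1r1 (3.05, SE 0.58) rose here too.

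Of 19 B cell markers 16 rose and 3 did not pass (17 rose when adjusted over the list alone), with a median of 2.58 (adjusted p = 2.23e-11, and adjusted p = 0.489 with an estimated correlation). Of 28 cell cycle genes 21 rose and 7 did not pass (23 rose when adjusted over the list alone), with a median of 0.98 (adjusted p = 8.65e-13, and adjusted p = 0.489 with an estimated correlation). Myeloid markers had a median of 1.90, with 9 of 18 rising and 1 falling (11 and 2 when adjusted over the list alone), and dendritic cell markers one of 1.65, with 5 of 10 rising (7 when adjusted over the list alone). Their adjusted p values were 0.00183 and 0.0117, and for both adjusted p = 0.698 with an estimated correlation. Noncanonical components that are also B cell or myeloid genes moved with those markers, namely Tnfrsf13c, the BAFF receptor (2.38, SE 0.31, and 1.39 on another probe), Cd40 (at least 10.4-fold higher) and Ltbr (1.62, SE 0.45). Relb, Traf3 (-0.43, SE 0.10) and Tnfrsf4 (-0.46, SE 0.14) fell and 9 did not pass (4 rose and 6 fell when adjusted over the list alone). The median of that list was 0.08, its mean 0.41 and its test downward (adjusted p = 0.686).

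Of 27 NF-kB target genes 6 fell and 21 did not pass (8 fell when adjusted over the list alone), with a median of -0.04, a mean of 0.04 and an adjusted p of 0.0648, and the list was not called with slide as a block either (0.14, adjusted p = 0.933). Of 19 regulatory T cell genes 6 fell, 1 rose and 12 did not pass (9 fell and 3 rose when adjusted over the list alone), with a median of -0.48 (adjusted p = 0.00505, and adjusted p = 0.698 with an estimated correlation). In the blocked model that median was -0.25 and not called (adjusted p = 0.297). Antigen-experienced T cell genes (median 0.30, 6 of 25 rising and 2 falling, 8 and 2 when adjusted over the list alone) and immediate early and heat shock genes (0.31, 5 of 16 rising in both adjustments) were called upward at adjusted p = 0.016 and 0.0212, with adjusted p = 0.698 for both with an estimated correlation. Among CD8 and NK cell markers, which were not called (median 0.45, adjusted p = 0.0902), Ncr1 rose by 2.58 (SE 0.41) and Gzma by 2.18 (SE 0.39). Plasma cell markers had a median of 1.09 (adjusted p = 0.0648), erythroid markers of 0.74 (adjusted p = 0.294) and platelet markers of 0.95 (adjusted p = 0.174). The median of the T cell identity list was 0.03 (adjusted p = 0.857).

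In total 2137 genes changed without nephritis, 1473 higher and 664 lower. The 2 IKK2 comparisons use no common array, and they shared 83 higher genes (14.55 expected of independent lists) and 111 lower genes (10.54 expected), with 2 and 4 opposite. Slide 2 held all 3 control arrays but only 1 knockout array, replicate 3, so a difference with slide as a block is that of this array from the controls. That array is also part of the unblocked mean, which favours a kept sign. On it the Th1 list stood at 0.996, against 0.25 and -0.13 on replicates 1 and 2, so lists called only with the block rest on 1 knockout array. With slide as a block 752 genes passed, all 2137 kept their sign, the median size went from 0.64 to 0.60 and the median SE from 0.141 to 0.192, and 36 of 81 named genes stayed past the threshold. Among these were Nfkbia (-0.72, SE 0.10), Ltb, Il4, Il7r, Zbtb16 and Bub1, whereas Il2 (-1.28, adjusted p = 0.0954), Lta (-0.50, adjusted p = 0.0689), Relb (-0.35, adjusted p = 0.270), Tnfaip3 (-0.36, adjusted p = 0.293), Il2ra (-0.91, adjusted p = 0.128) and Lrrc32 (-1.73, adjusted p = 0.0756) no longer passed. On slide 2 alone 201 genes passed. In the blocked model the median was 2.82 for B cell markers and 1.32 for the cell cycle list, both called, and Th1 (0.84, adjusted p = 2.08e-05), Th17 (1.12, adjusted p = 0.000297), naive (-0.25, adjusted p = 0.0152), plasma cell (1.56, adjusted p = 0.0152) and CD8 and NK cell lists (0.49, adjusted p = 0.0271) were called as well, while the antigen-experienced median went to 0.58 and the immediate early and heat shock median to 0.20. The count without Cre control replicate 2 was 1339 and without replicate 3 it was 1264, and with the B cell marker mean as a covariate it was 8 (limma, 1593 at an unadjusted p under 0.05). Normexp gave 1361 genes, and a fit of only the arrays compared 920.

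**Figure D3:**
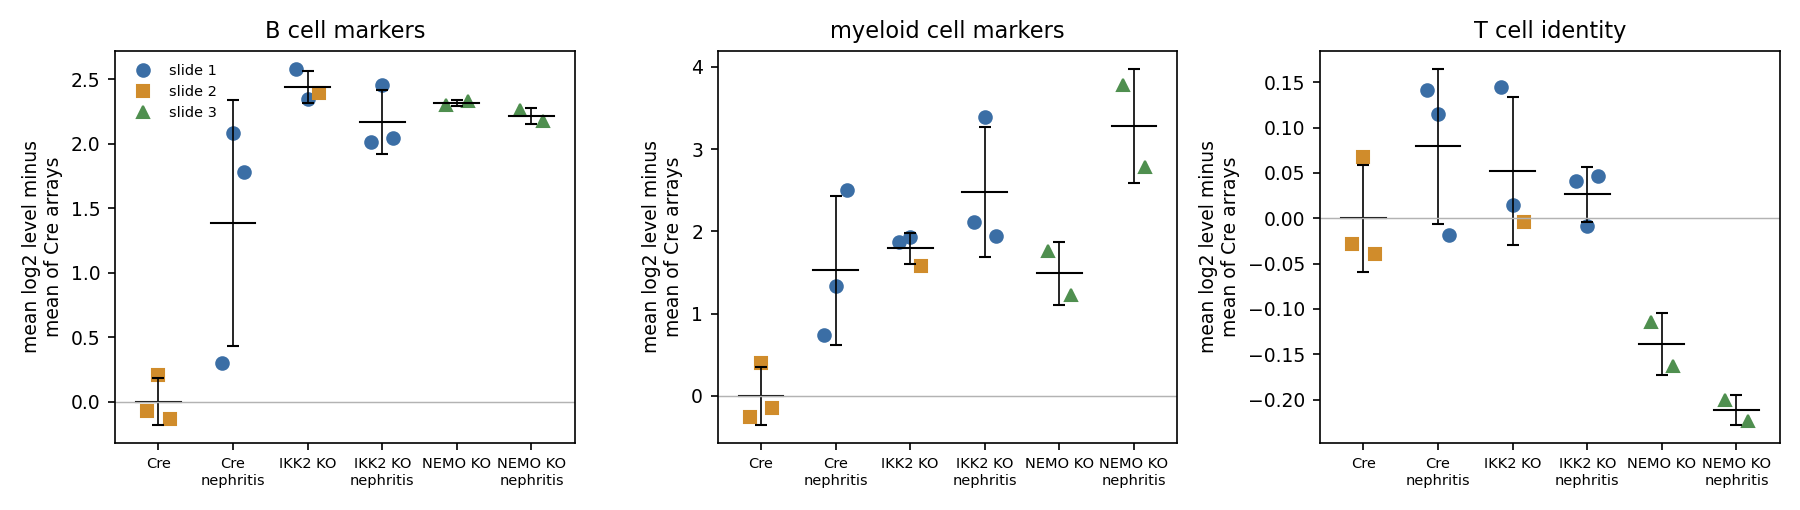
Mean log2 level of B cell markers, myeloid cell markers and T cell identity genes on each array, relative to the mean of the Cre control arrays without nephritis. Group means of the B cell markers rise to 2.44 in IKK2 knockout arrays without nephritis, while those of the T cell identity genes stay between -0.21 and 0.08.

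NEMO knockout arrays were compared with Cre controls in each condition to ask what the loss of the regulatory subunit changes. Without and with nephritis, 14 and 15 of 17 naive and central T cell genes fell, while 14 and 13 of 16 Th1, 12 and 11 of 13 Th17 and 17 and 19 of 25 antigen-experienced T cell genes rose. These lists were called by camera, but none with an estimated correlation (lowest adjusted p = 0.176 without and adjusted p = 0.165 with nephritis). Bach2, a repressor of effector differentiation, fell by 1.78 without nephritis and 2.83 with it (SE 0.12 each). Gzmb, the cytotoxic protease granzyme B, rose by 4.12 and 3.13 (SE 0.30 each), Il1r1 by 6.74 and 6.81 (SE 0.65 each) and Il17re by 6.47 and 6.31 (SE 0.62 each). The mitotic kinase genes Bub1 (3.65 and 3.06, SE 0.24 each) and Plk1 (2.33 and 2.34, SE 0.15 each) rose as well, and the survival gene Bcl2 fell by 1.31 and 1.38 (SE 0.13 each).

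Without nephritis, 14 of 17 naive and central T cell genes fell and 3 did not pass, and with nephritis 15 fell and 2 did not pass (16 when adjusted over the list alone). The list medians were -1.42 (adjusted p = 2.89e-09) and -1.94 (adjusted p = 1.52e-09), with adjusted p = 0.176 and adjusted p = 0.165 with an estimated correlation. Of 28 cell cycle genes 26 and then all 28 rose (medians 2.82 and 2.57), and of 13 Th17 genes 12 and 11 rose (3.30 and 3.33, with 12 rising in both conditions when adjusted over the list alone). The adjusted p values of these lists were 6.72e-18 and 2.93e-19 for the cell cycle and 3.02e-07 and 1.97e-07 for Th17, again with adjusted p = 0.176 and adjusted p = 0.165 with an estimated correlation. Of 16 Th1 genes 14 and 13 rose, likewise when adjusted over the list alone, among them Nkg7 (2.19 and 2.49, SE 0.33 each), the IL-18 receptor Il18r1 (2.64 and 2.58, SE 0.32 each, and 4.33 on another probe with nephritis) and, with nephritis, Ifng (3.98, SE 0.53). The Th1 medians were 2.12 and 2.41 (adjusted p = 8.73e-07 and 7.05e-08, with adjusted p = 0.380 and adjusted p = 0.281 with an estimated correlation). Antigen-experienced T cell genes rose in 17 and 19 of 25 cases, with 1 and 3 falling (18 rising when adjusted over the list alone without nephritis), including Lgals1 (2.40 and 2.31, SE 0.16 each) and Anxa2 (2.94 and 2.46, SE 0.17 each). Their medians were 1.82 and 1.63 (adjusted p = 1.94e-08 and 1.45e-08, and adjusted p = 0.176 and adjusted p = 0.165 with an estimated correlation).

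NF-kB target genes were called upward in both conditions, with 15 rising and 3 falling of 27 without nephritis and 13 rising and 4 falling with it (15 and 4, and 14 and 4, when adjusted over the list alone). Their medians were 0.65 and 0.57 (adjusted p = 0.00924 and 0.0018, with adjusted p = 0.405 and adjusted p = 0.381 with an estimated correlation). The growth factor gene Csf2 rose by 2.47 and 2.95 (SE 0.36 each) and the anti-apoptotic Bcl2a1d by 1.61 and 1.56 (SE 0.22 each), while Myc fell in both conditions, by 1.18 (SE 0.18) without nephritis. Of 15 noncanonical components 6 rose, 1 fell and 8 did not pass without nephritis, and 4 rose, 3 fell and 8 did not pass with it, with the same counts when adjusted over the list alone, and that list was not called (medians 0.14 and 0.13, adjusted p = 0.222 and 0.371). Nfkb2, the p100 precursor of that pathway, rose by 0.49 and 0.58 (SE 0.14 each), the costimulatory receptor Tnfrsf4 by 0.46 and 0.69 (SE 0.16 each), and Cd27 fell by 1.82 and 2.11 (SE 0.12 each). Of 20 canonical components 6 rose and 6 fell, and with nephritis 4 rose and 7 fell (5 and 8 when adjusted over the list alone), with falls of 0.33 and 0.46 for Rela (SE 0.09 each) and 0.61 and 0.70 for Prkcq (SE 0.11 each). That list was not called (adjusted p = 0.867 and 0.999).

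Further T cell lists moved. Regulatory T cell genes rose in 9 and 10 of 19 cases with 2 and 3 falling (11 and 3 without nephritis when adjusted over the list alone), with medians of 0.72 and 0.98. Follicular helper genes rose in 6 of 15 with 1 falling in each condition (8 and 1 with nephritis when adjusted over the list alone), with medians of 0.79 and 1.20, and the list included Icos (1.35 and 1.11, SE 0.15 each) and Maf (2.38 and 2.16, SE 0.44 each). Adjusted p values without and with nephritis were 0.026 and 0.0173 for the regulatory list and 0.041 and 0.0176 for the follicular list, with adjusted p between 0.425 and 0.499 with an estimated correlation. Interferon response genes were called downward with nephritis, where 13 of 27 fell and 3 rose (14 and 3 when adjusted over the list alone), with Oas2 at -2.55 (SE 0.29) and a median of -0.59 (adjusted p = 0.0316, and adjusted p = 0.627 with an estimated correlation). The glycolysis list was called upward (0.30 and 0.13, adjusted p = 0.0174 and 0.0316, with adjusted p = 0.447 and adjusted p = 0.449 with an estimated correlation), with Hk2 higher by 3.38 and 2.46 (SE 0.32 each) and Pfkm lower by 0.67 and 0.96 (SE 0.10 each). Th2 (1.01 and 0.68, adjusted p = 0.133 and 0.0831), apoptosis regulator (0.23 and 0.12, adjusted p = 0.068 and 0.0625) and T cell identity lists (-0.18 and -0.26, adjusted p = 0.244 and 0.0804) were not called.

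Markers of other cells moved with these T cell lists in both conditions. CD8 and NK cell markers had medians of 1.10 and 1.27 (adjusted p = 0.0106 and 0.00164), B cell markers 2.98 and 0.57 (adjusted p = 1.12e-05 and 0.04), plasma cell markers 2.02 and 1.01 (adjusted p = 0.00769 and 0.027), myeloid markers 1.65 and 1.57 (adjusted p = 0.0227 and 0.00164) and dendritic cell markers 2.65 and 1.82 (adjusted p = 0.00246 and 0.00101). With nephritis, the B cell list stood at 2.26 and 2.18 on the NEMO arrays, relative to untreated Cre controls. It stood at 0.30, 2.08 and 1.78 on control replicates 1 to 3, so that shift leans on control replicate 1. Platelet markers were called with nephritis (1.42, adjusted p = 0.027) and not without it (0.39, adjusted p = 0.645). Erythroid markers without nephritis had a median of -0.01 and a mean of 0.31 and were not called (adjusted p = 0.867). With an estimated correlation the adjusted p values of the called marker lists lay between 0.381 and 0.551.

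Without nephritis 6315 genes changed (3087 higher, 3228 lower) and with nephritis 7095 (2758 higher, 4337 lower), relative to a median of all genes of -0.06 and -0.14. Both comparisons shared 2304 higher and 2610 lower genes (580 and 954 expected of independent lists), and they use no common array. All NEMO arrays lay on slide 3, which held no other genotype, so that slide and genotype cannot be told apart here, and only a random slide block could be fitted. It left 5116 and 5555 genes past the threshold and kept 92 of 101 and 100 of 106 named genes. The B cell marker mean as a covariate left 1405 genes without nephritis.

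The knockouts were set against each other under nephritis, which the series title names as its question. In NEMO knockout arrays 14 of 17 naive and central T cell genes were lower than in IKK2 knockout arrays, 14 of 16 Th1, 12 of 13 Th17 and 19 of 25 antigen-experienced T cell genes were higher, and single NF-kB genes differed in both directions. Of the 14 lists called, 0 were called with an estimated correlation (lowest adjusted p = 0.179). Nfkb2 was higher by 1.23 (SE 0.14), Relb by 0.89 (SE 0.14), Traf3, an inhibitor of the noncanonical pathway, by 0.68 (SE 0.11), Tnfrsf4 by 1.12 (SE 0.16) and Il2 by 4.09 (SE 0.32). Map3k14, the kinase NIK that starts that pathway, differed by -0.67 (SE 0.12), and Cd27 differed by -1.81 (SE 0.12). Ccr7, the lymph node homing chemokine receptor, differed by -3.35 (SE 0.15) and Bcl2 by -2.29 (SE 0.13), whereas Gata3 was higher by 1.11 (SE 0.09) and Il2ra by 2.72 (SE 0.29).

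Of 27 NF-kB target genes 19 were higher, 1 was lower and 7 did not pass (19 and 3 when adjusted over the list alone), with a median of 0.89 (adjusted p = 6.17e-06, and adjusted p = 0.179 with an estimated correlation). Of 15 noncanonical components 6 were higher, 3 lower and 6 did not pass (6 and 4 when adjusted over the list alone), with a median of 0.46 that was not called (adjusted p = 0.217). Of 20 canonical components 7 were higher and 5 lower, likewise when adjusted over the list alone (median 0.07, adjusted p = 0.521). Of 19 regulatory T cell genes 15 were higher and 3 lower, and of 11 Th2 genes 8 were higher and 3 lower, with the same counts when adjusted over each list alone. Their medians were 1.59 and 2.03 (adjusted p = 1.24e-05 and 0.00533, with adjusted p = 0.240 and adjusted p = 0.179 with an estimated correlation). Th1 (14 of 16 higher, median 2.67), Th17 (12 of 13 higher and 1 lower, 3.30), cell cycle (25 of 28 higher, 2.14), antigen-experienced (19 of 25 higher and 2 lower, 1.96) and follicular helper genes (8 of 15 higher and 1 lower, 1.15) were called upward. Naive and central T cell genes were called downward (14 of 17 lower, -1.79). When adjusted over the list alone, 3 antigen-experienced genes were lower, 9 follicular helper genes higher and 1 naive gene higher, and the other counts of these lists were the same. The adjusted p values of these 6 lists lay between 6.85e-16 and 0.00515, with adjusted p between 0.179 and 0.345 with an estimated correlation. The glycolysis list was called upward too (6 of 16 higher and 1 lower, likewise when adjusted over the list alone, median 0.18, adjusted p = 0.018, and adjusted p = 0.468 with an estimated correlation).

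CD8 and NK cell markers (median 1.31, adjusted p = 0.00123), plasma cell markers (1.89, adjusted p = 0.0035), dendritic cell markers (1.01, adjusted p = 0.0162) and myeloid markers (0.93, adjusted p = 0.0457) were called upward as well, with adjusted p between 0.327 and 0.588 with an estimated correlation. B cell markers were not (0.38, adjusted p = 0.764), with 4 of 19 lower, Cd79a by a log2 difference of -0.95 (SE 0.35), and 1 lower when adjusted over the list alone. The T cell identity list had a median of -0.15 (adjusted p = 0.18), with Cd3d at -0.55 (SE 0.11). In total 6767 genes differed, 2783 higher and 3984 lower in the NEMO knockout. The genotypes lay on different slides, with 5283 genes and 90 of 106 named genes passing with slide as a random block, under which the myeloid list was no longer called (1.02, adjusted p = 0.0575).

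**Figure D4:**
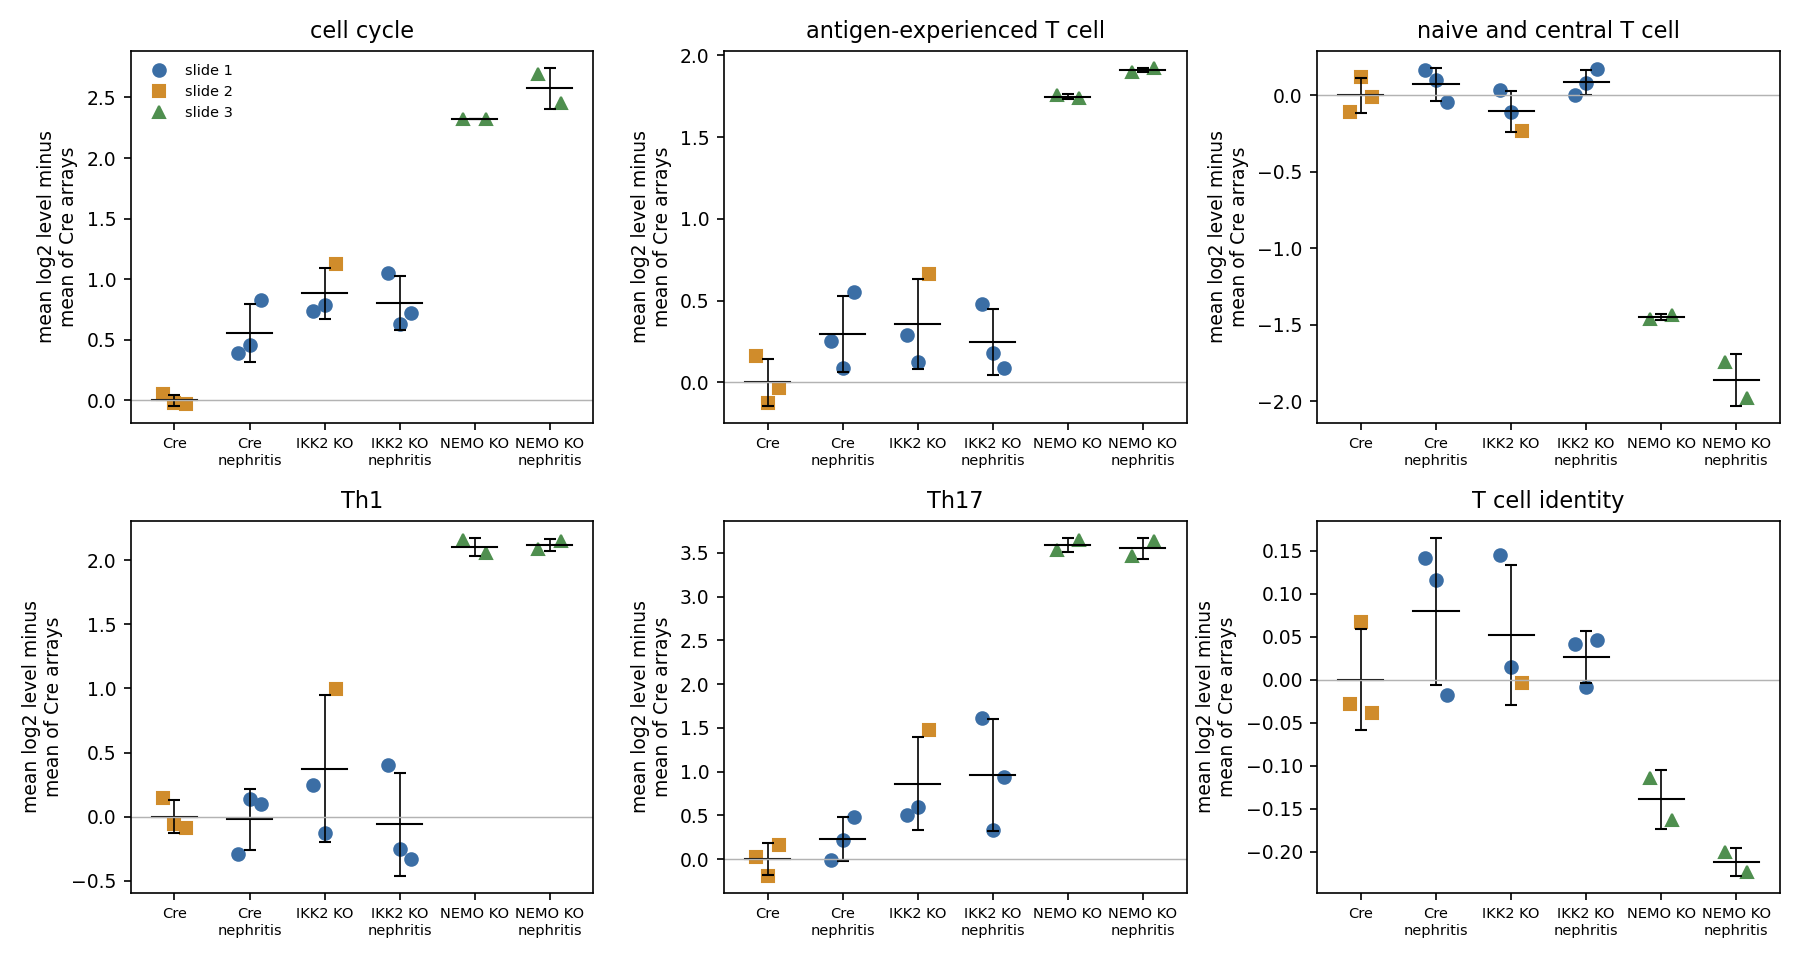
Mean log2 level of 6 gene lists on each array, relative to the mean of the Cre control arrays without nephritis, by group. The cell cycle list reaches group means of 2.32 and 2.58 in NEMO knockout arrays, and the naive list falls to -1.45 and -1.86, while the T cell identity list stays between -0.21 and 0.08.

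Nephritis was then compared with no nephritis within each genotype. In Cre controls, 1 of 11 erythroid markers, 6 of 19 B cell markers and 6 of 28 cell cycle genes were higher on day 10, and the shifts of the 3 lists, called by camera but not with an estimated correlation, differed in size between arrays. Relative to the untreated mean, the erythroid list stood at 0.43, 1.74 and 4.17 on replicates 1 to 3 with nephritis, the B cell list at 0.30, 2.08 and 1.78 and the cell cycle list at 0.39, 0.45 and 0.83. Aqp1, the red cell water channel, was at least 29.8-fold higher and Klf1, the erythroid master factor, at least 3.14-fold higher. Cd79b rose by 1.81 (SE 0.25), Mzb1, a plasma and marginal zone B cell gene, by 2.80 (SE 0.54), and the mitotic gene Ube2c by 1.12 (SE 0.26). Il1rl1 rose by 1.36 (SE 0.21), the follicular helper regulators Ascl2 and Bcl6 by 1.92 (SE 0.44) and 0.37 (SE 0.09), Gzmb by 1.10 (SE 0.27), and Il10 was at least 2.18-fold higher, whereas the neutrophil elastase gene Elane fell by 0.81 (SE 0.13).

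Of 28 cell cycle genes 6 rose and 22 did not pass (22 rose when adjusted over the list alone), with a median of 0.63 (adjusted p = 1e-06, and adjusted p = 0.676 with an estimated correlation). B cell markers rose in 6 of 19 (10 when adjusted over the list alone) and erythroid markers in 1 of 11 (7 when adjusted over the list alone), with medians of 1.59 and 2.25 (adjusted p = 2.24e-05 and 0.0062, and adjusted p = 0.676 for both with an estimated correlation). Myeloid (1.68), plasma cell (1.58), Th2 (0.36), follicular helper (0.30), antigen-experienced (0.35), interferon (0.46) and glycolysis lists (0.20) were called upward and platelet markers downward (-0.43), at adjusted p from 0.0062 to 0.0459, with adjusted p between 0.676 and 0.755 with an estimated correlation. NF-kB target genes had a median of 0.13 (adjusted p = 0.608), and none of the 27 passed in limma (3625 of all genes had an unadjusted p under 0.05). The naive list had a median of 0.07 with a test downward (adjusted p = 0.874).

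Here 592 genes changed, 377 higher and 215 lower, against a median of all genes of 0.10. The authors' matrix gave 140 of 322 higher (43.5% against 63.7%), and a percentile over probes above background on all arrays gave 223 of 469 higher (47.6%). The control groups lay on different slides, and with slide as a block, estimated through the IKK2 arrays, all 592 genes kept their sign while the median size went from 0.75 to 0.63 and the median SE from 0.149 to 0.259, and 2 genes passed. Of the 36 named genes 1 passed with the block, Lgals3 (2.26, SE 0.27). The blocked medians were 1.57 for B cell markers and 1.06 for the cell cycle list, both called, while erythroid (1.39, adjusted p = 0.0907), glycolysis (0.09, adjusted p = 0.266) and platelet lists (-0.16, adjusted p = 0.384) were not, and the Th1 list turned from -0.11 to 0.92 (adjusted p = 7.71e-06). The block also called NF-kB target (0.38, adjusted p = 0.00011), regulatory T cell (0.51, adjusted p = 0.000271), Th17 (1.31, adjusted p = 0.000767), dendritic cell (1.16, adjusted p = 0.00424) and noncanonical component lists (0.31, adjusted p = 0.0367) upward, and moved the antigen-experienced median to 0.64, the Th2 median to 0.62 and the myeloid median to 1.02. The block's offset between slides 1 and 2 rests on untreated IKK2 knockout replicate 3, the only array of its group on slide 2. On it the Th1 list stood at 0.996, against 0.25 and -0.13 on replicates 1 and 2, so the Th1 turn rests on 1 array. Without Cre control replicate 1, 2 or 3 of the untreated group the count of changed genes was 114, 273 or 199, and without replicate 2 or 3 of the nephritis group it was 198 or 224. Without both arrays that stood apart it was 63, and with the B cell marker mean as a covariate 32. Normexp gave 167 genes, of which 49.7% were higher, no filter on dim probes gave 234, and limma on only the arrays compared called 0, with 2891 at an unadjusted p under 0.05.

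In the IKK2 knockout, genes of several kinds changed with nephritis. Tsc22d3, the glucocorticoid-induced leucine zipper, rose by 1.46 (SE 0.19), the RNA decay factor Zfp36l2 by 1.42 (SE 0.17) and the pro-apoptotic Bbc3 by 1.30 (SE 0.19). The NF-kB inhibitor genes Nfkbia and Tnfaip3 rose by 0.58 (SE 0.07) and 1.01 (SE 0.16), Cd69 by 1.04 (SE 0.12) and Bcl2 by 0.87 (SE 0.12), while the heat shock gene Hsph1 fell by 1.38 (SE 0.21).

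Of the 23 lists 4 were called. Naive genes (median 0.19, adjusted p = 0.00112, with 5 of 17 rising when adjusted over the list alone) and interferon genes (0.31, adjusted p = 0.00112) shifted up. Th1 genes (-0.46, adjusted p = 0.00879) and CD8 and NK cell markers (-0.64, adjusted p = 0.0201, with 4 of 14 falling when adjusted over the list alone) shifted down, and for all 4 the adjusted p was 0.909 with an estimated correlation. A slide block ended the Th1 and the CD8 and NK cell calls (-0.07, adjusted p = 0.645, and -0.52, adjusted p = 0.0794). Altogether 65 genes changed, 36 higher and 29 lower. Under this block 54 genes passed, 33 of them shared, and 15 of 20 named genes (not Apol7c, Arrdc3, Ddit4, Dusp1 and Itgb3). On slide 1 alone, with 3 against 2 arrays, limma called 0 genes, with 1689 at an unadjusted p under 0.05. The count was 163 and 31 without untreated replicate 1 and 2, and 124, 17 and 8 without nephritis replicate 1, 2 and 3. It was 36 without both arrays that stood apart, 41 with normexp, 33 with no filter on dim probes, 161 with quantile normalisation (49.1% higher against 55.4%), 130 with a filter of 8 arrays and 149 with a percentile over probes above background on all arrays. Limma on only the arrays compared called 0 genes, with 1629 at an unadjusted p under 0.05.

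In the NEMO knockout, Bach2 fell with nephritis by 0.91 (SE 0.13) and the neuronal splicing factor Rbfox3 by 3.91 (SE 0.56). Bst1, an ectoenzyme of bone marrow stromal and myeloid cells, rose by 1.81 (SE 0.27). Dntt, the terminal transferase of lymphocyte precursors, rose by 1.04 (SE 0.18), and Rag1, of the recombinase of the same cells, was at least 1.59-fold higher. Of 17 naive genes 1 fell and 16 did not pass (7 fell when adjusted over the list alone), with a median of -0.41 (adjusted p = 4.39e-11, and adjusted p = 0.314 with an estimated correlation). Cell cycle (0.26, adjusted p = 1.29e-08, and adjusted p = 0.451 with an estimated correlation), follicular helper (0.31, adjusted p = 3.97e-06), myeloid (0.85, adjusted p = 1.68e-08) and erythroid lists (1.67, adjusted p = 2.07e-05) shifted up, the last 3 with adjusted p = 0.314, 0.314 and 0.451 with an estimated correlation. NF-kB target (0.16), antigen-experienced (0.14), interferon (0.09), plasma cell (0.46), dendritic cell (0.34) and CD8 and NK cell lists (0.34) were also called, at adjusted p from 0.00963 to 0.0266 and adjusted p from 0.562 to 0.667 with an estimated correlation.

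All 4 arrays of that comparison lay on slide 3, and 61 genes changed, 9 higher and 52 lower. With slide as a block 64 passed, 57 of them shared, and all 11 list shifts were called on slide 3 alone, whereas limma on these 4 arrays called 0 genes, with 1727 at an unadjusted p under 0.05. Neither fit could change the differences, which rest on the same 4 arrays, so kept calls do not test for a slide effect. The authors' matrix gave 11 genes, all lower (0% higher against 14.8%), and normexp gave 13. The count was 40 and 30 without untreated replicate 1 and 2, 23 without nephritis replicate 2, and 35 without both Cre control arrays that stood apart. Of the genes changed by nephritis, Cre control and IKK2 knockout had 2 higher and 2 lower in common (0.925 and 0.425 expected of independent lists) and 1 going opposite ways, and Cre control and NEMO knockout had 3 higher and 2 lower (0.231 and 0.762 expected) and 1 opposite. IKK2 and NEMO knockout shared 0 higher and 0 lower genes (0.0221 and 0.103 expected), and 2 went opposite ways.

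Whether the nephritis response itself differed between genotypes was tested directly. Nephritic Cre controls all lay on slide 1 and untreated ones on slide 2. Without a slide block, a slide effect may therefore be part of these differences. For the IKK2 knockout against Cre control, 166 genes differed, 44 with a higher and 122 with a lower response. Tsc22d3 responded more by 1.65 (SE 0.27) and Cd69 by 0.94 (SE 0.17), and the responses of Il1rl1 and Hsph1 differed by -2.16 and -1.77 (SE 0.29 each). For B cell genes the difference was negative, with Cd79b at -2.49 (SE 0.35) and a B cell marker median of -1.77. Of 19 markers 3 fell and 16 did not pass (7 fell when adjusted over the list alone). Relative to untreated Cre controls, these markers averaged 1.39 in nephritic Cre controls, and 2.44 and 2.17 in untreated and nephritic IKK2 knockout arrays. They mark other cells, and whether the T cells themselves responded differently was not tested by them. The list's adjusted p was 1.46e-05, and adjusted p = 0.886 with an estimated correlation. For the NEMO knockout 39 genes differed, 2 higher and 37 lower, against a median of all genes of -0.13. Bach2 differed by -1.05 (SE 0.17), and the naive list had a median of -0.46 (adjusted p = 1.49e-05, and adjusted p = 0.774 with an estimated correlation), which went to -0.21 (adjusted p = 0.0116) with slide as a block. Under this block 38 and 1 genes passed, and 3 of 24 named genes for the IKK2 knockout (Hsph1, Il1rl1 and Tsc22d3) and 0 of 9 for the NEMO knockout, Bach2 (-1.24, adjusted p = 0.209) included. A percentile over probes above background on all arrays gave 52 of 121 higher for the IKK2 knockout (43.0% against 26.5%). The IKK2 count was 32, 59 and 13 without untreated Cre control replicate 1, 2 and 3, and 391, 15 and 30 without nephritic Cre control replicate 1, 2 and 3. It was 69, 35 and 349 without untreated IKK2 knockout replicate 1, 2 and 3, and 21 and 9 without nephritic IKK2 knockout replicate 2 and 3. The NEMO count was 18, 15 and 16 without untreated Cre control replicate 1, 2 and 3, 19 without nephritic Cre control replicate 2, 18 and 13 without untreated NEMO knockout replicate 1 and 2, and 13 without nephritic replicate 2. Without both arrays that stood apart the counts were 3 and 9. Further counts were 17 and 0 with normexp (limma, 867 at an unadjusted p under 0.05 for the latter), 31 and 1 with the authors' matrix, 10 and 15 with no filter on dim probes, 4 and 14 with the B cell covariate and 11 and 5 with only the arrays compared. For the NEMO knockout quantile normalisation gave 21 and the percentile over probes above background 23.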

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

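The tests of explanations in this part were chosen only after the result was seen, apart from the test of B cell genes outside the marker list and the splits of the samples, which were set before the data were examined. The response contrasts, the slide block as an alternative fit and the omission of each array were also set before. The response differences that follow stand here because they passed a test of the difference itself, with adjusted p under 0.05. The control response in that test compares slide 1 with slide 2, so slide may be part of these differences. The B cell markers, the effector and naive genes and the genes around Ikbkb do not stand here by that rule.

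The response of the IKK2 knockout differed from that of the Cre control in 166 genes, 9 to 391 when an array was left out (without nephritic IKK2 knockout replicate 3 and nephritic Cre control replicate 1). Responses were higher in the knockout for Arrdc3 (1.71), Bbc3 (1.33), Cd69 (0.94), Chrm3 (1.65), Dusp1 (1.42), Gnal (1.72, and 0.83 on another probe), Majin (2.11), Ppp1r14bl (1.69), Tnfsf8 (0.56) and Tsc22d3 (1.65). They were lower for the B cell genes Cd79b (-2.49), Tnfrsf13c (-2.29, and -1.46 on another probe) and Vpreb3 (-3.81), for the myeloid and eosinophil genes Ear1 (-3.76), Ear2 (-3.91) and Lyz1 (-2.92), and for Fn1 (-3.95), Gfra2 (-3.74), Mgst1 (-4.13), Klre1 (-1.94), Il1rl1 (-2.16), Hsph1 (-1.77) and Ikbkg (-0.78). List medians of the difference were 0.12 for naive genes, -0.59 for antigen-experienced genes, -0.74 for the cell cycle, -0.18 for glycolysis, -1.77 for B cell markers and -2.34 for plasma cell markers. The slide block takes its offset between slides 1 and 2 from untreated IKK2 knockout replicate 3, the only knockout array on slide 2. The blocked values that follow rest on that array, whose Th1 list stood at 0.996 against 0.25 and -0.13 on replicates 1 and 2. With slide as a block, Hsph1 (-2.10, adjusted p = 0.0478), Il1rl1 (-2.48, adjusted p = 0.0361) and Tsc22d3 (1.89, adjusted p = 0.0478) stayed past the threshold among the named genes, and the glycolysis list was no longer called (-0.17, adjusted p = 0.0672). The block newly called Th1 (-1.04, adjusted p = 1.02e-05), regulatory T cell (-0.65, adjusted p = 0.00184), Th2 (-0.34, adjusted p = 0.0129), NF-kB target (-0.37, adjusted p = 0.0221), CD8 and NK cell (-1.04, adjusted p = 0.0323) and dendritic cell lists (-1.25, adjusted p = 0.0461) downward, and moved the naive median to 0.30.

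The response of the NEMO knockout differed from that of the Cre control in 39 genes, 13 to 50 when an array was left out (without untreated NEMO knockout replicate 2 and nephritic Cre control replicate 1). Acta2 differed by 1.12, Bach2 by -1.05, Rbfox3 by -4.33 and Vpreb3 by -3.54, and with slide as a block 0 of the 9 named genes passed. Adgrl2 (-4.15), Crx (-4.91), Slc17a2 (-4.13), Slc24a4 (-5.32) and Vmn2r16 (-4.65) were not well above background on any nephritic NEMO knockout array, so these fitted values are not folds of measured levels. Here too the slide block takes its offset between slides 1 and 2 from untreated IKK2 knockout replicate 3, so the blocked list values rest on that array. List medians were -0.46 for naive genes, -1.35 for B cell markers and 0.90 for platelet markers, of which the platelet shift was no longer called with slide as a block (0.66, adjusted p = 0.153) and the naive median went to -0.21 (adjusted p = 0.0116). That block newly called NF-kB target (-0.31), Th1 (-0.92), Th17 (-1.52), regulatory T cell (-0.43), antigen-experienced (-0.48), cell cycle (-0.82) and interferon lists (-0.41) downward, at adjusted p from 5.52e-06 to 0.0390.

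Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real split gave 592 genes for nephritis in Cre controls, 65 for nephritis in the IKK2 knockout, 2137 for the IKK2 knockout without and 378 with nephritis, each as large as 1 of 10 splits, and the highest other values were 15, 3, 11 and 1. Called lists numbered 11, 4, 7 and 11 in the same order, with highest other values of 13, 12, 8 and 14, so that 2, 8, 3 and 6 of the 10 splits gave as many. For the response difference of the IKK2 knockout, 2 of 100 splits drawn from 200 gave 166 genes or more, a share under 0.05. The splits exchange nephritis labels within each genotype, so they address an absence of any nephritis effect, not equal responses. They therefore cannot decide whether the responses differ between genotypes. The splits took no account of slide, and with slide as a block 38 genes passed, so that an effect of slide on this count is not excluded by them. The highest other value of 227 came from the split that exchanges the Cre control labels alone and thus adds both responses. For lists, 55 of the 100 splits gave 6 or more (highest other 15), so chance is not excluded there.

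B cell markers were higher in IKK2 knockout than in Cre control arrays without nephritis, although the cells had been sorted as CD4+. The rise over these controls was not particular to the IKK2 knockout. Relative to untreated Cre controls, the list averaged 2.44 in untreated IKK2 and 2.32 in untreated NEMO knockout arrays. It averaged 1.39 in nephritic Cre controls (0.30, 2.08 and 1.78 by array). What set the untreated Cre controls apart was not tested. Fewer T cells would raise markers of all other cells alike only if those cells kept equal shares. The median of the erythroid markers lay 1.84 (SE 0.40) and that of the platelet markers 1.63 (SE 0.31) below that of the B cell markers. This argues against an equal rise of all other cells, but not against fewer T cells as such. The medians of myeloid (1.90), dendritic cell (1.65) and plasma cell markers (1.09) were higher too. B cells or their RNA among the sorted cells may contribute, since 10 of 16 B cell genes outside the marker list rose and 0 fell past the limma threshold (4404 of all genes had an unadjusted p under 0.05), with a median of 2.11, and the 2 markers with the brightest probes, H2-Eb1 (log2 level 6.32 against 2.81) and H2-Ab1 (6.14 against 2.74), rose too, though 15 of 19 markers were well above background on all 3 Cre control arrays. Slide as the cause cannot be decided here. With a fixed slide block the marker median was 2.82 in place of 2.58, but that is the same value as on slide 2 alone. There, 1 knockout array (replicate 3) stands against the 3 controls. Its B cell list stood at 2.40 and the highest control at 0.21, so the difference was seen within a slide, on 1 knockout array. A difference in the spleens of the knockout mice stays open as well and was not tested.

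Effector genes, here the Th1, Th17 and antigen-experienced lists (14 of 16, 12 of 13 and 19 of 25), were higher and naive genes (14 of 17) lower in NEMO knockout than in IKK2 knockout arrays with nephritis, with no list called with an estimated correlation (lowest adjusted p = 0.179). Fewer T cells among the sorted cells are argued against by the T cell identity median of -0.15, which lay 1.64 (SE 0.36) above that of the naive genes. CD8 T or NK cells, which the CD4 sort should remove, may contribute to the rise of effector genes, as 2 lineage genes, Ncr1 (1.57, SE 0.45) and Klrb1c (1.75, SE 0.44), rose, while Cd8a differed by 1.20 (SE 0.48) and Cd8b1 by -1.27 (SE 0.18), and Gzma, with the brightest probe of their 14 markers, read a log2 level of 5.44 against 3.94. For the fall of naive genes such cells are argued against by Cd4, which they lack and which differed by 0.019 (SE 0.107). Slide cannot be told apart from genotype, because 0 arrays of another genotype lay on slide 3, and an effect of NEMO loss on T cell differentiation stays open beside it.

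Genes around Ikbkb, though not its closest neighbours, changed in the IKK2 knockout in both conditions. They were 10 of the 200 tested genes around it (5%, against 1.32% of all 14674 ordered genes), chosen after their values were seen. Counted in tested genes along the chromosome, the nearest lay at places 23 (Hgsnat) and -24 (Agpat5) from Ikbkb. Cd209c lay at place -85, and the others lay between 40 (Tti2) and 55 (Saraf). Lower genes included Tti2 (-1.79 and -1.69) and Hgsnat (-1.17 and -1.26), and higher ones Fut10 (2.53 and 2.33), Cd209c (1.84 and 2.53) and Mboat4 (1.06 and 1.47). A chromosome segment carried along with the floxed allele is a candidate explanation: of 62 other windows of that size, 1 held as many (highest 10, median 2), and the window around Ikbkg held 0 (limma called 2137 genes without and 378 with nephritis). Mismatches under the probes alone are argued against by the 3 higher genes, 1 of which (Fut10) had another probe, also higher. Cd209c was higher in the NEMO knockout too (2.55 and 2.91), so its rise was not particular to the IKK2 knockout. Of the 10 genes 2 changed the same way in the NEMO knockout, where 30.5% of the window and 33.5% of all genes changed in both conditions, and an effect of IKK2 loss on these genes was not tested apart from the segment.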

How the results depend on the processing

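The omission of 2 arrays that stood apart and the B cell marker covariate were chosen only after the data were seen. The cause of the changes given here was not tested, except where fewer arrays or fewer genes were used by construction. The main counts of changed genes were 592, 65 and 61 for nephritis in Cre control, IKK2 and NEMO knockout, 2137 and 378 for the IKK2 knockout without and with nephritis, 6315 and 7095 for the NEMO knockout, 6767 between the knockouts, and 166 and 39 for the response differences of IKK2 and NEMO. The counts of the NEMO comparisons with other genotypes stayed within 1.5 times under all alternatives but the 2-fold threshold, all probes and, without nephritis, the B cell covariate. Signal over background sets a limit: 14675 of 20660 genes had a probe well above background on 2 arrays, and 27 of them lacked a value on an array.

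Normexp background correction gave 167, 41 and 13 genes for nephritis in the 3 genotypes, 1361 and 202 for the IKK2 knockout, and 17 and 0 for the response differences (limma, 867 at an unadjusted p under 0.05 for the last). The authors' matrix gave 322 for nephritis in Cre controls, 11 in the NEMO knockout, and 31 and 1 for the response differences. With no filter on dim probes the counts were 234 and 33 for nephritis in Cre control and IKK2 knockout, 198 for the IKK2 knockout with nephritis, and 10 and 15 for the response differences. For nephritis in the IKK2 knockout, quantile normalisation gave 161, a filter of 8 arrays 130 and a percentile over probes well above background 149. For the NEMO response difference quantile normalisation gave 21 and that percentile 23.

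Slide as a fixed block gave 2 genes for nephritis in Cre controls, 752 for the IKK2 knockout without nephritis, and 38 and 1 for the response differences, and 106 of 223 named genes stayed past the threshold. The block could not change differences between arrays of 1 slide, as for the IKK2 knockout with nephritis and nephritis in the NEMO knockout. It called 70 list shifts against 53 over the same 7 comparisons, 45 of them shared in direction. It turned the Th1 list upward for nephritis in Cre controls (0.92), and in the NEMO response difference it turned the NF-kB target (-0.31), Th1 (-0.92), Th17 (-1.52) and regulatory T cell lists (-0.43) downward. These turns rest on untreated IKK2 knockout replicate 3, the only array of its group on slide 2. A random slide block gave 26 for nephritis in Cre controls and 39 and 15 for the response differences. On slide 1 alone 0 genes passed for nephritis in the IKK2 knockout (limma, 1689 at an unadjusted p under 0.05) and 73 for the IKK2 knockout with nephritis, with 10 of 60 named genes. On slide 2 alone 201 genes, 22 of 81 named genes and 11 list shifts against 7 passed for the IKK2 knockout without nephritis. On slide 3 alone 0 genes and 0 of 13 named genes passed for nephritis in the NEMO knockout (limma, 1727 at an unadjusted p under 0.05).

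The replicate numbers did not pair the samples: of 36 pairs of arrays with the same number, 3 had a correlation of deviations over 0.1 (range -0.199 to 0.126). The replicate block gave 32 and 39 genes for nephritis in the IKK2 and NEMO knockout and 8 and 19 for the response differences, with other counts within 1.5 times, and 96 list shifts against 97. With only the arrays compared, limma called 0 genes for nephritis in each genotype (2891, 1629 and 1727 at an unadjusted p under 0.05), 920 and 49 for the IKK2 knockout, and 11 and 5 for the response differences. Without both arrays that stood apart the counts were 63, 36 and 35 for nephritis, 208 for the IKK2 knockout with nephritis, and 3 and 9 for the response differences.

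With the B cell marker mean as a covariate the counts were 32 for nephritis in Cre controls, 8 and 145 for the IKK2 knockout, 1405 for the NEMO knockout without nephritis, and 4 and 14 for the response differences, and 305 of 536 named genes stayed past the threshold. The covariate reversed, for the IKK2 knockout without nephritis, Batf3 (-0.55), C1qc (-1.44), Cd40 (-1.56), Clec4a4 (-2.17), Csf1r (-0.15), Fcer1g (-0.19), Flt3 (-1.25), Gp5 (-0.64), Itgax (-0.90), Klra7 (-0.53), Ltbr (-1.06) and Vcam1 (-2.07). For the NEMO knockout without nephritis it reversed Batf3 (-0.13), Cd40 (-1.51), Itgax (-0.43), Ltbr (-0.15) and Tyrobp (-0.55). For the NEMO knockout with nephritis, normexp reversed Blk (-0.19) and Gp1bb (-0.036), quantile normalisation and the authors' matrix each reversed Lck (0.16), and the other Ikbkg probe gave 0.015. For the IKK2 knockout without nephritis that probe gave 0.34, which did not pass.

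At a 2-fold threshold the counts were 216 and 22 for nephritis in Cre control and IKK2 knockout, 717 and 122 for the IKK2 knockout, 2462, 2708 and 2518 for the NEMO comparisons and 88 for the IKK2 response difference. With all probes they were 1089 and 136 for nephritis in Cre control and IKK2 knockout, 3832 for the IKK2 knockout without nephritis, and 13553, 14336 and 14855 for the NEMO comparisons. With an estimated correlation 0 of 97 list shifts were called by camera, and the other alternatives over 10 comparisons called 94 to 111. Leaving out 1 array gave 114 to 847, 8 to 163 and 23 to 48 genes for nephritis in the 3 genotypes, 1264 to 2324 and 121 to 252 for the IKK2 knockout, 9 to 391 and 13 to 50 for the response differences, and 83 to 195 named genes, of 125 and 234 compared. The lowest counts came without untreated Cre control replicate 1 (114) and 3 (1264), nephritic IKK2 knockout replicate 3 (8 and 9) and 2 (121), nephritic NEMO knockout replicate 2 (23) and untreated NEMO knockout replicate 2 (13). The highest came without nephritic Cre control replicate 1 (847, 252, 391 and 50), untreated IKK2 knockout replicate 1 (163) and 3 (2324) and nephritic NEMO knockout replicate 1 (48).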

Other observations

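Apoptosis regulators, interferon genes and NF-kB receptor genes held further differences between the genotypes, given here as values. Under nephritis, NEMO knockout arrays exceeded Cre control arrays by 3.37 (SE 0.40) in Pmaip1, which encodes the pro-apoptotic NOXA, and by 0.99 (SE 0.11) in Fasl, the death ligand, with Bcl2 at -1.38 (SE 0.13). In the IKK2 knockout under nephritis Bcl2 was higher by 0.91 (SE 0.12). Of 21 apoptosis regulators 9 rose and 4 fell in the NEMO knockout with nephritis, and 1 rose and 1 fell in the IKK2 knockout (2 and 2 when adjusted over the list alone). Between the knockouts Bcl2 differed by -2.29 (SE 0.13) and the list's median by 0.18 (adjusted p = 0.131).

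The interferon-induced genes Ifit2 and Oasl1 were lower in the NEMO knockout without nephritis (-2.22, SE 0.15, and -1.62, SE 0.25) and with it (-2.01, SE 0.15, and -2.48, SE 0.25). The interferon list as a whole was not called by camera without nephritis (median -0.24, adjusted p = 0.118). Tnfrsf26, a decoy receptor of the TNF family, was at least 191-fold lower in the NEMO knockout than in Cre controls with nephritis and at least 209-fold lower than in the IKK2 knockout, and Mal, a T cell membrane proteolipid, was at least 81.7-fold higher in the NEMO knockout without nephritis. Among cytokine receptors Il4ra fell in the NEMO knockout by 1.47 (SE 0.17) without and 2.19 (SE 0.17) with nephritis on 1 probe but by 0.28 and 0.099 on another, whereas Il23r, the IL-23 receptor, was at least 25.1-fold higher with nephritis. The 4 arrays of the NEMO knockout lay on a slide of their own.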
